A study of Homo sapiens with 12 samples.

How the data were processed

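RNA abundance was measured in 12 libraries of 8505c cells, a line from a human anaplastic thyroid carcinoma. Per the labels' protocols, total RNA was isolated with column kits and TruSeq libraries were sequenced paired-end, 2 × 100 bases, on an Illumina NextSeq instrument. Cells carried lentiviral Cas9 together with a guide vector whose cassette was either empty (control) or held a guide that the labels name as targeting AHR (the labelled knockout). Each kind of cell was collected at day 0 (labelled DMSO) and after 4 days with dabrafenib at 10 µM and trametinib at 10 nM, which gives 4 groups of 3 libraries. Dabrafenib inhibits BRAF and trametinib inhibits MEK. The series text prints the dabrafenib dose without its prefix, and the dose given here is the one on the sample labels. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. A label states that the second read was not provided for replicate 2 of the labelled knockout at day 0.

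The authors deposited a table of read counts per gene name for the 6 day 0 libraries and another for the 6 libraries collected after the drugs. The counts were whole numbers whose sums differed between libraries, with no scaling. Per the submitters' processing notes, the genome build was GRCh38.p14 and the authors used DESeq2. The aligner, the counting tool, its handling of strand and of reads with several matches, the annotation release and the DESeq2 version were not given in the sources used here. Reads shared between related or near-identical genes (HLA class I genes, histone genes, AKR1C genes, CYP1A1 and CYP1A2, haemoglobin genes) or between a gene and one that overlaps it could therefore have been divided in ways that cannot be checked. The authors also deposited, for labelled knockout against control in each state, log2 fold changes and adjusted p-values per gene. Those 2 tables were used only for a comparison with the values computed here.

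Each count table had 60609 lines in the same order of names. The 2566 lines without a name held 0.061% to 0.118% of a library's counts and were left out of library sizes and tests. Another 27 lines carried dates in place of gene names (25 different dates), held 0.144% to 0.217% of the counts, and were left out too. The 199 names found on several lines (1763 lines, of which 1585 had names of RNA families) held 0.441% to 0.756% of the counts and were summed per name. This left 56452 names. Over all lines, total counts ran from 12792324 to 19874080 for control cells at day 0, 16552202 to 19723052 for control cells after the drugs, 12909811 to 25084428 for the labelled knockout at day 0 and 16444032 to 19626008 for the labelled knockout after the drugs. The labels state a larger number of reads per sample. CPM below stands for counts per 1e6.

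Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): genes passing filterByExpr with a minimum count of 10, TMM scaling, 4 group means fitted over all 12 libraries with robust quasi-likelihood dispersions and 8 residual degrees of freedom, and Benjamini-Hochberg adjustment over the 15579 genes tested within each comparison. A gene was called at an adjusted p under 0.05. The 5 comparisons were labelled knockout against control at day 0 and after the drugs, drugs against day 0 in each kind of cell, and the difference between both drug responses (an interaction). The drugs and the 4 days in culture could not be separated, because no untreated library was collected at day 4. These comparisons also cross the 2 deposited count tables. The standard error of a log2 fold change was the fold change divided by the square root of its F statistic. CPM values are given as mean ± SD of 3 libraries. Where a group had 0 counts for a gene, a fold is a lower bound against 3 counts over the whole group, and where it had 1 to 3 counts the ratio of counts is given with its 95% interval. These bounds and intervals cover counting error only.

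Gene lists were tested with camera on the same fit, with the correlation between genes preset to 0.01, two-sided, and Benjamini-Hochberg adjustment over the 28 lists of a comparison. The test was repeated with an estimated correlation, with fry, and with the replicate number as a block. The lists, the comparisons, the test and the rule for naming genes were fixed before the data were examined. The rule as fixed did not exclude RNA family names, and it did not waive the overlap requirement for the interaction. That requirement has no direct form for 4 groups. Both changes were made when the rule was applied. The rule took AHR, the 10 genes with the highest and the 10 with the lowest fold change in each knockout comparison and in the drug comparison of control cells (called, mean CPM of at least 5 over the 6 libraries, no overlap between the groups, uncharacterised loci, pseudogenes and RNA family names left out), 6 and 6 for the interaction (mean CPM over all 12 libraries, without the overlap requirement), up to 4 members per list and comparison by adjusted p (at most 2 where none was called), and all members of the AhR target and ERK lists. For drugs against day 0 in the labelled knockout it took only the genes already taken in control cells and list members. A few genes outside this rule are identified where they appear as chosen after their values were seen. Some genes taken by the rule, and the list with 1 gene measured, are not reported here. Old symbols in the counts (CTGF, CYR61, HIST1H1B and others) are kept as deposited.

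Positions came from GENCODE release 44 on GRCh38, matched by symbol for 37140 names, of which 987 matched through an older symbol. The guide sequence printed in the labels was searched on both strands of the primary chromosomes of GRCh38. For positions along chromosomes, the 12817 positioned genes with a mean of at least 1 CPM on chromosomes 1 to 22 and X were divided into windows of 50 neighbouring genes, each window's median log2 fold change was set against the median of all genes, and gene positions were permuted 1000 times. This scan, its window size and its threshold of 0.2 were chosen after the data had been seen.

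The count test was tried on simulated counts made from the real means, dispersions and library sizes, with 200 genes of at least 1 CPM changed in each comparison. For labelled knockout against control at day 0 it recovered 31.3% of genes changed by 0.5 on the log2 scale, 91% of those changed by 1 and 97% of those changed by 2. For the interaction these shares were 9%, 58.2% and 90.9%. Far more genes were called in the real comparisons, which loosens the adjusted threshold, so these shares do not carry over directly to the data. Replicates were compared before they were averaged. No pair of libraries within a group differed by as little as sampling noise, since the lowest ratio of chi-square to degrees of freedom among the 12 pairs was 4.3. All were counted as separate samples. Alternatives were size factors by RLE, no composition factor, no count filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, a replicate block, stricter thresholds, fits of only the 6 libraries compared, and leaving out each library. An alternative chosen after seeing the data removed the 5 small structured RNAs RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP before scaling. Their share of the counts was 5.9% to 7.9% in control cells at day 0, 2.4% to 3.4% in the labelled knockout at day 0, 7.9% to 8.6% in control cells after the drugs and 9.2% to 10.7% in the labelled knockout after the drugs.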

Results

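RNA was sequenced from 12 libraries of 8505c cells, a line from an anaplastic thyroid carcinoma. Control cells carried Cas9 and an empty guide cassette, and the other cells carried a guide labelled as targeting AHR, the aryl hydrocarbon receptor, a ligand-activated transcription factor. Each kind of cell was measured at day 0 and after 4 days with the BRAF inhibitor dabrafenib (10 µM) and the MEK inhibitor trametinib (10 nM), with 3 libraries per group. Total counts per library ran from 12792324 to 25084428, and 13268 to 14991 genes per library had at least 10 counts. The first principal component held 64.5% of the variance and separated libraries collected after the drugs from those of day 0. The second held 19.4% and separated the labelled knockout from control cells. The series title gives the loss of AHR and resistance to therapy against mutant BRAF as the subject of the study. Whether the replicates were separate cultures was not stated, so every p-value measures only the spread between these libraries. Nothing measured here separates an effect of the guide from other differences between both kinds of cell. The shifted chromosome stretches described below may be among those differences.

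AHR transcripts were present in every library, those labelled knockout included. In control cells AHR stood at 135, 122 and 145 CPM (counts per 1e6) in the 3 libraries of day 0 and at 430, 436 and 407 CPM after the drugs. In the labelled knockout it stood at 72.1, 96.3 and 89.2 CPM at day 0 and at 93.6, 96.5 and 92.3 CPM after the drugs. The log2 fold change of labelled knockout against control was -0.64 ± 0.10 (SE, 3 libraries per group) at day 0 and -2.17 ± 0.10 after the drugs, with adjusted p of 0.000204 and 1.62e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The authors' deposited tables give AHR -0.67 and -2.17 for the same comparisons. An edit that leaves the transcript in place would not be seen in gene counts, so the AHR level alone does not settle the genotype.

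The guide printed in the labels, CGTAAGATGGTTAGCTTGTC, had 1 exact match in GRCh38, on chromosome 1 at 150839529 to 150839548 on the plus strand, followed by the PAM TGG. That site lies in coding exon 6 of ARNT transcript ARNT-202 (exon at 150839441 to 150839654). ARNT (chromosome 1, 150809713 to 150876708, minus strand, ENSG00000143437.21) encodes the nuclear partner with which AHR binds DNA, and it also pairs with hypoxia-inducible factors. The closest 20-base window in AHR (chromosome 7, 16916359 to 17346152, plus strand, ENSG00000106546.14) had 5 mismatches. ARNT was chosen after its values were seen. Its transcript did not pass the test in the labelled knockout, with a log2 fold change of 0.12 (adjusted p 0.338) at day 0 and -0.05 (adjusted p 0.704) after the drugs. Scaled by total counts alone, which moved the median of all genes by -0.191 after the drugs, ARNT did pass there with -0.24 (adjusted p 0.0419). Mean ARNT levels were 26.8 ± 2.49 CPM (SD, n = 3) in control and 29.3 ± 3.08 CPM in labelled knockout cells at day 0. After the drugs they were 47.7 ± 1.58 and 46.1 ± 2.90 CPM. Because the printed guide matches ARNT and not AHR, the cells are called the labelled knockout throughout, and every direction below refers to that label.

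**Figure D1:**
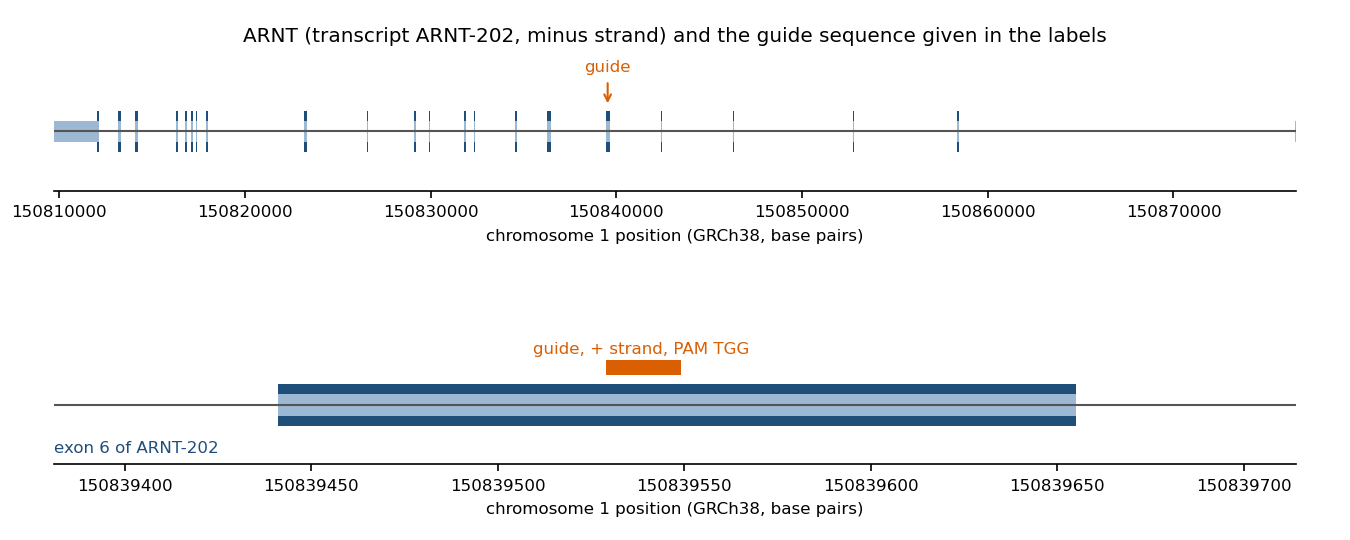
Exons of ARNT transcript ARNT-202 along chromosome 1 (position in bases, GRCh38), with the site matched by the printed guide marked. The match at 150839529 to 150839548 lies within coding exon 6.

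**Figure D2:**
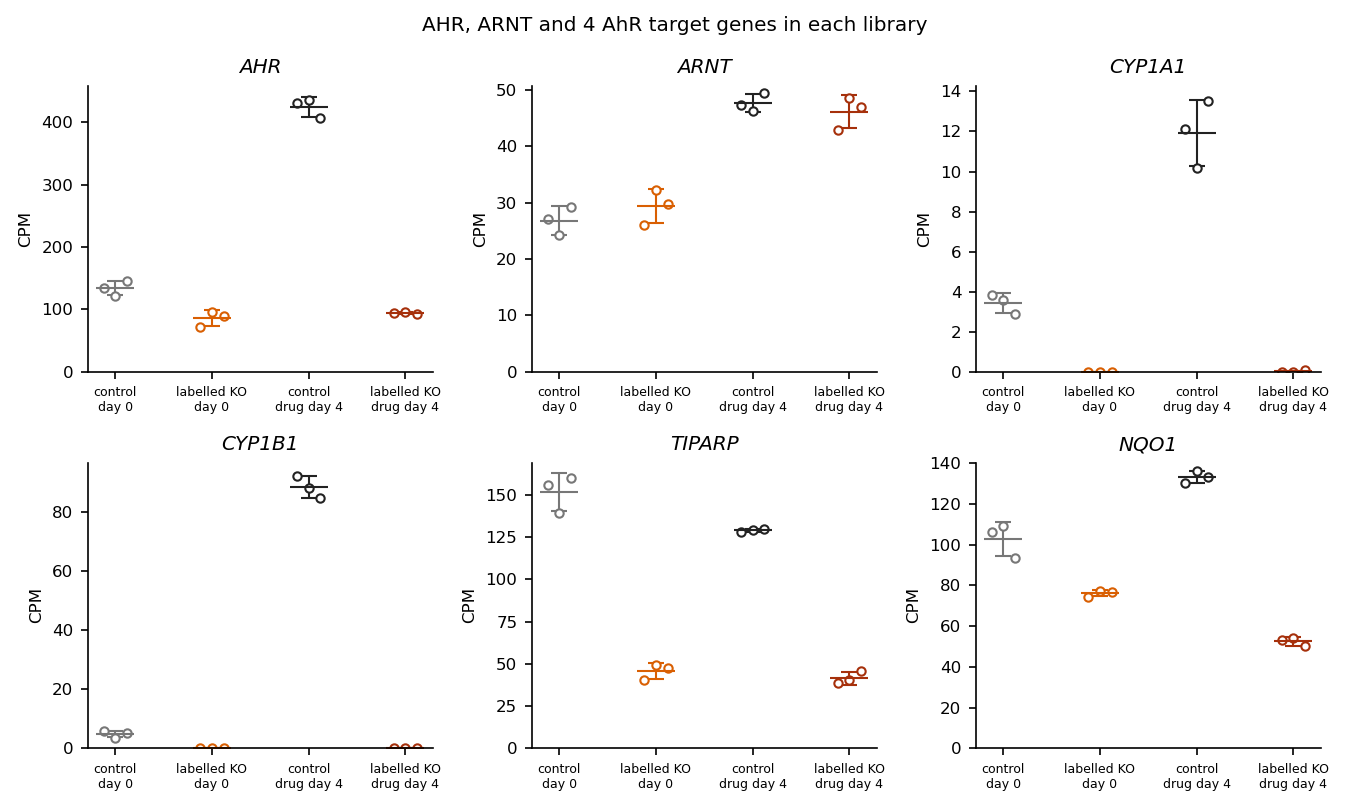
Counts per 1e6 of AHR, ARNT, CYP1A1, CYP1B1, TIPARP and NQO1 in each library (points), with the mean and SD of the 3 libraries of each of the 4 groups. CYP1B1 averaged 88.2 CPM in control cells after the drugs and 0.0189 CPM in the labelled knockout, while ARNT averaged 47.7 and 46.1 CPM.

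Labelled knockout against control at day 0 asks what the guide's cells express differently before treatment. The AHR targets CYP1A1 and CYP1B1, which encode cytochrome P450 enzymes that oxidise aromatic compounds, had no counts in any of the 3 labelled knockout libraries. Against a floor of 3 counts over the group, CYP1A1 was at least 67-fold lower and CYP1B1 at least 97.4-fold lower. TIPARP, which encodes an ADP-ribosyltransferase that restrains AHR, fell from 152 ± 11.2 to 45.6 ± 4.81 CPM (log2 fold change -1.74 ± 0.09, adjusted p 9.82e-09). CYP1A2 was at least 3.29-fold lower on 8 counts in control cells, and how reads that match CYP1A1 as well were counted is not known. Other members moved apart: KYNU of tryptophan breakdown rose by 2.06 on the log2 scale and NFE2L2, a regulator of antioxidant genes, by 0.48, while AHRR, the AHR repressor, did not pass the test (adjusted p 0.981). Of 17 measured AHR targets, 2 were higher and 9 lower, with the same counts adjusted over the list alone. The list ranked low (camera, median log2 fold change -1.74, or -1.72 with genes at 0 set to their bounds, adjusted p 2.26e-08), and it is the only list called in this comparison that was also called with an estimated correlation (adjusted p 0.0264).

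MMP1, a collagenase, fell at day 0 from 11990 ± 602 to 103 ± 13.5 CPM (log2 fold change -6.86 ± 0.13, adjusted p 5.69e-13), and the stromelysin MMP3 fell too (-5.82). SERPINB2, an inhibitor of plasminogen activators, changed by -8.91, the metalloprotease ADAMTS9 by -7.39, and PTGS2, which encodes the inducible prostaglandin synthase, by -6.10. PTGS2 lies in a stretch of chromosome 1 whose genes were shifted upward in the labelled knockout. The transcription factor SIM2 and the adhesion gene DSCAM lie on chromosome 21, whose genes were shifted downward. With TMEM200A and PARM1 they were the other 4 of the lowest 10 taken by the rule for naming genes, together with ALDH1A3, which encodes a retinaldehyde dehydrogenase. The related ALDH1A1 went the other way, from 1.04 to 118 CPM. The imprinted noncoding RNA H19 rose from 0.169 ± 0.0463 to 54.0 ± 4.29 CPM (log2 fold change 8.29 ± 0.16, adjusted p 5.47e-13), as did the mechanosensitive channel PIEZO2 (7.47), the basement-membrane collagen COL4A4 (7.40) and the lipoprotein receptor OLR1 (7.17). LUZP2, the small heat-shock gene CRYAB, the myosin kinase MYLK, ARHGAP28 and ADGRG2 (in a shifted stretch of chromosome X) completed the highest 10 taken by the rule, which leaves out genes with a mean under 5 CPM and genes whose groups overlap. In all, 6712 of 15579 genes were called, 3633 higher and 3079 lower, and 1876 of them changed at least 2-fold, 732 higher and 1144 lower.

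Genes that respond to ERK signalling were lower at day 0. The phosphatase genes DUSP4 and DUSP6 changed by -1.20 and -1.37 on the log2 scale, and the early-response factors EGR1 and FOSL1 by -2.07 and -0.99. Of 19 measured genes of ERK output, 0 were higher and 15 lower (1 and 15 adjusted over the list alone; camera adjusted p 9.21e-08, and adjusted p 0.14 with an estimated correlation). Inflammatory genes went 4 higher and 11 lower of 20 (4 and 12 adjusted over the list alone; adjusted p 5.27e-05, and adjusted p 0.197 with an estimated correlation). CXCL1, a neutrophil chemokine, fell by 2.24, while the adhesion receptor ICAM1 rose by 2.35. Receptor tyrosine kinases and their ligands went 4 higher and 12 lower of 22, with the same counts adjusted over the list alone (adjusted p 0.0303, and adjusted p 0.273 with an estimated correlation). HGF, the ligand of MET, changed by -2.95 and EGFR by -0.94. Antigen presentation genes went 0 higher and 7 lower of 15 (0 and 10 adjusted over the list alone; adjusted p 0.0339, and adjusted p 0.395 with an estimated correlation).

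Replication, cholesterol and mitochondrial genes were higher at day 0 in the labelled knockout. Of 27 genes of G1/S and DNA replication, 17 were higher and 0 lower (18 and 0 adjusted over the list alone; camera adjusted p 0.000136, and adjusted p 0.262 with an estimated correlation). The helicase subunit MCM6 rose by 0.83 and E2F8, a repressor of cell-cycle genes, by 1.23. Of 22 genes of cholesterol synthesis, 15 were higher and 1 lower, also adjusted over the list alone (adjusted p 0.00474, and adjusted p 0.488 with an estimated correlation), with HMGCS1 up by 1.09. Transcripts of the mitochondrial genome went 10 higher and 0 lower of 13 (11 and 0 adjusted over the list alone; adjusted p 0.0347, and adjusted p 0.824 with an estimated correlation). Their share of the counts varied widely within the group, from 1.3% to 2.83% in the labelled knockout against 0.87% to 1.38% in control cells. The endothelial list of 3 genes was called upward (adjusted p 0.000949, and adjusted p 0.14 with an estimated correlation) although its median log2 fold change was -0.32 and its mean 0.93. That call rests on CDH5, which encodes VE-cadherin and rose from 7.46 to 109 CPM. HBB, a haemoglobin gene, was called higher with counts in 2 of the 3 labelled knockout libraries. The call was lost with DESeq2 (adjusted p 0.0541), with limma-voom (adjusted p 0.763) and without control replicate 1, 2 or 3 or labelled knockout replicate 2 of day 0.

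Labelled knockout against control after the drugs asks how the cells differ once BRAF and MEK are inhibited. CYP1A1 and CYP1B1, which rose with the drugs in control cells, stayed near 0 in the labelled knockout. CYP1B1 had 88.2 ± 3.77 CPM in control cells and 1 count in the labelled knockout, a ratio of 4310 with a 95% interval of 773 to 170000. CYP1A1 had a ratio of 577 (103 to 22800), and ALDH3A1, an aldehyde dehydrogenase, was at least 17.9-fold lower. The list went 0 higher and 15 lower of 17, also adjusted over the list alone, with a median of -2.02 and a camera adjusted p of 4.68e-15 (adjusted p 0.00121 with an estimated correlation). NQO1, a quinone reductase, changed by -1.34, the EGFR ligand EREG by -3.14 and TIPARP by -1.64 ± 0.10.

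Antigen presentation and interferon genes were far lower in the labelled knockout after the drugs. HLA-B averaged 1819 ± 60.8 CPM in control and 104 ± 3.21 CPM in labelled knockout cells (log2 fold change -4.13 ± 0.09, adjusted p 3.04e-12). HLA-C changed by -2.15. How reads that match several class I genes were counted is not known, which leaves the separate sizes uncertain. Antigen presentation went 0 higher and 14 lower of 15, also adjusted over the list alone (adjusted p 5.33e-17, and adjusted p 0.00611 with an estimated correlation). The interferon list went 1 higher and 23 lower of 25, also adjusted over the list alone (adjusted p 2.61e-14, and adjusted p 0.016 with an estimated correlation). IFIT3, an antiviral effector, changed by -2.24, the factor IRF1 by -1.55, and STAT2, in a stretch of chromosome 12 whose genes were shifted downward, by -1.69. CXCL1 fell by 4.33 within an inflammatory list of 4 higher and 11 lower of 20, also adjusted over the list alone (adjusted p 0.016, and adjusted p 0.326 with an estimated correlation).

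Glycolytic and hypoxia-responsive genes were higher in the labelled knockout after the drugs. Of 25 genes 23 were higher and 2 lower, also adjusted over the list alone, with a median log2 fold change of 1.15 and a camera adjusted p of 5.33e-17 (adjusted p 0.00611 with an estimated correlation). PDK1, a kinase that inhibits pyruvate dehydrogenase, rose by 2.02, the mitophagy gene BNIP3 by 1.65 and hexokinase HK2 by 1.57. Oxidative phosphorylation went 17 higher and 0 lower of 23, also adjusted over the list alone (adjusted p 0.00449, and adjusted p 0.331 with an estimated correlation). Cholesterol synthesis went 17 higher and 2 lower of 22 (18 and 2 adjusted over the list alone; adjusted p 8.98e-05, and adjusted p 0.295 with an estimated correlation). Mitotic genes went 15 higher and 1 lower of 25, also adjusted over the list alone (adjusted p 0.0157, and adjusted p 0.326 with an estimated correlation), at low levels: FOXM1, a driver of mitotic transcription, had 1.64 CPM in control and 4.99 CPM in labelled knockout cells, against 158 and 195 CPM at day 0. Genes of G1/S and DNA replication, with 13 higher and 3 lower of 27, were not called after the drugs (camera adjusted p 0.214).

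The highest fold changes after the drugs included CGA, the shared subunit of thyrotropin and related hormones, at 12.7 ± 1.21 CPM in control and 1164 ± 88.0 CPM in labelled knockout cells (log2 fold change 6.52 ± 0.13, adjusted p 3.04e-12). USH1C (6.54), the secreted C1QL1 (5.93), the adhesion gene TENM2 (5.88), DAW1, PIEZO2, SEMA5B, GLP2R, ALDH1A1 and KISS1 made up the rest, of which GLP2R and KISS1 lie in shifted stretches of chromosomes 17 and 1. The lowest 10 held CYP1B1 and CYP1A1, the membrane-traffic gene MAL2 (ratio 663, 119 to 26200), the transporter SLC16A9 (-8.02), the actin regulator MTSS1 (ratio 224, 76.3 to 1090), MXRA5 (-7.61, in the shifted stretch of chromosome X), PARM1, LY75, MBNL3 and CYP4B1. BMF, which encodes a pro-apoptotic BCL2 relative, stood at 41.9 CPM in control and 0.692 CPM in labelled knockout cells. ERK output went 3 higher and 12 lower of 19, also adjusted over the list alone (adjusted p 0.00457, and adjusted p 0.326 with an estimated correlation). In all, 8382 genes were called, 4095 higher and 4287 lower, and 2987 changed at least 2-fold, 1062 higher and 1925 lower. Scaled by total counts alone the median of all genes moved by -0.191 and 31.5% of called genes were higher, against 48.9%. None of the called lists changed the sign of its median under any scaling tried.

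The differences of both states overlapped in part. Of 4219 genes called at day 0 and after the drugs, 1719 were higher in both, 1587 lower in both and 913 opposite. Calls made independently over all genes tested would give 955 higher and 847 lower in both. The correlation across genes, which are not independent replicates, was 0.48 (Spearman 0.36). In the authors' deposited tables, at an adjusted p under 0.05, day 0 had 4905 called genes and the drug comparison 8917. Of these, 4812 and 7876 were called here too, all in the same direction except 1 after the drugs.

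Some chromosome stretches shifted as blocks between labelled knockout and control. The 430 genes of chromosome 14 had a median log2 fold change of -0.56 relative to genes elsewhere at day 0 and -0.54 after the drugs. Of these genes 63.7% and 62.3% were called lower, against 19.4% and 26.2% of 12387 genes on other chromosomes. The drugs moved chromosome 14 genes by 0.06 in control and 0.05 in labelled knockout cells. Medians of 258 windows of neighbouring genes correlated between states at 0.66, above the highest of 1000 permutations of gene positions (0.41, permutation p 0.001, the smallest they can give). Window medians of both drug responses correlated at 0.87, so such a correlation alone does not mark a shift of chromosome stretches. Runs of windows past 0.2 in both states were chromosome 1 at 154155308 to 248906196 (0.45 and 0.40), chromosome 12 at 49636499 to 64759484 (-0.30 and -0.33), chromosome 14 at 19062316 to 105489855 (-0.52 and -0.53), chromosome 17 at 212389 to 18667629 (0.27 and 0.42) and chromosome X at 276322 to 44873188 (0.47 and 0.35). The 1336 genes in these runs were called in 66.5% of cases at day 0 and 69.2% after the drugs, against 45.1% and 55.8% of 11481 genes elsewhere. AHR and ARNT lie outside the runs, and 30 of 297 positioned genes taken by the rule for naming genes lie inside. The guide match at 150839529 lies shortly before the run on chromosome 1. Its own window (145992435 to 150960583) had medians of -0.19 at day 0 and -0.49 after the drugs. The next window had -0.13 and -0.01, and the run follows. Whether the run is related to a cut at that site was not tested. Chromosome 21 (132 genes, relative medians -0.20 and -0.31) was shifted downward without forming such a run. Chromosome 12 as a whole had relative medians of -0.15 and -0.19. Single windows past 0.2 in both states lay outside the runs too. Examples are chromosome 8 from 124488485 (-0.387 and -0.327), chromosome 17 from 43014607 (-0.305 and -0.307) and, upward, chromosome 2 from 169694454 (0.284 and 0.319). A gene outside the runs may therefore still lie in a shifted stretch.

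**Figure D3:**
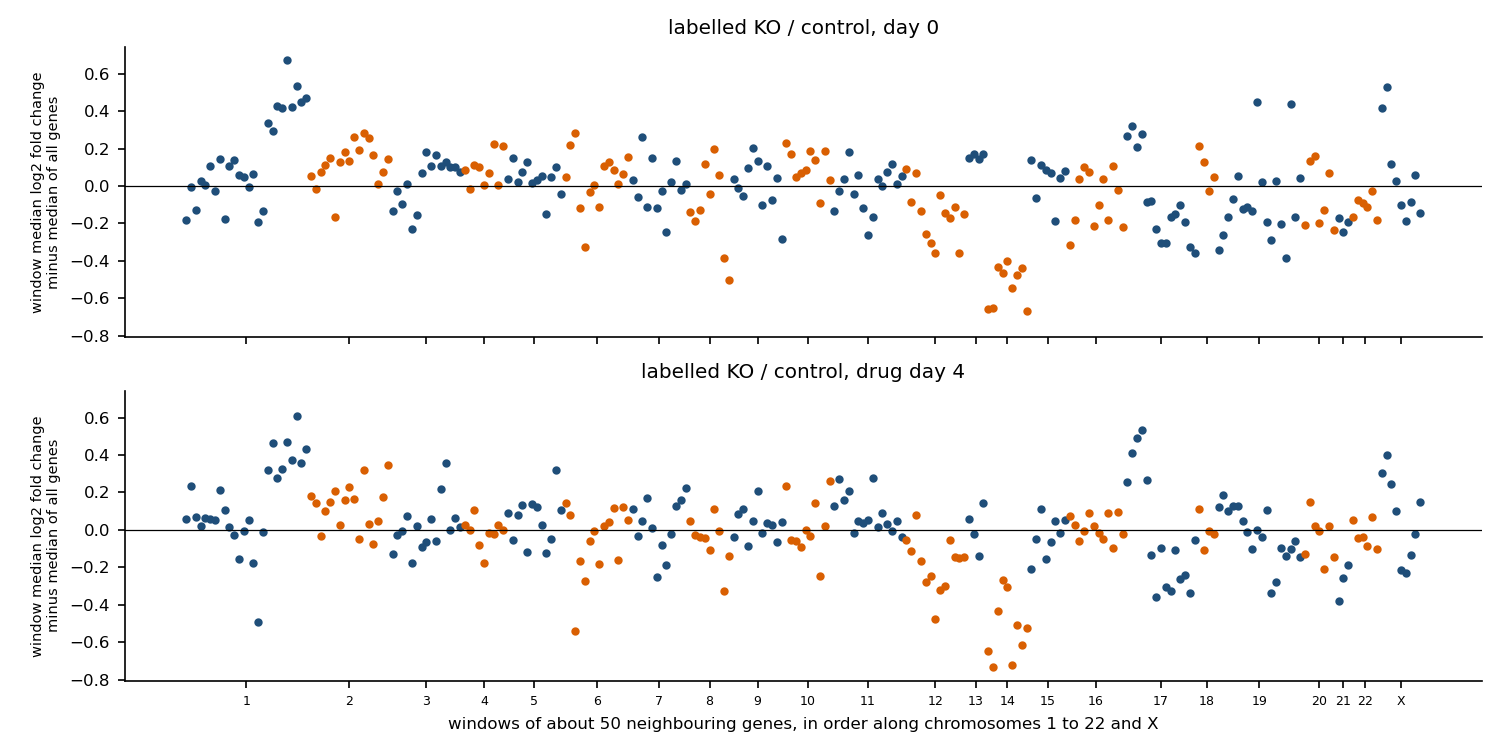
Median log2 fold change of labelled knockout against control in windows of 50 neighbouring genes, less the median of all genes, along the chromosomes at day 0 and after the drugs. All 9 windows of chromosome 14 lie below 0 in both states, from -0.67 to -0.40 at day 0.

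Drugs against day 0 in control cells asks what 4 days of BRAF and MEK inhibition change. The time in culture cannot be separated from the drugs, and the counts of both time points came in separate tables. Output of the ERK pathway fell: cyclin CCND1 changed by -4.64 on the log2 scale, DUSP6 by -7.73, the ERK inhibitor SPRY4 by -8.43 and the factor ETV4 by -9.26. The list went 1 higher and 18 lower of 19 (camera adjusted p 3.11e-23, and adjusted p 0.00905 with an estimated correlation). Proliferation genes fell with it. All 27 genes of G1/S and DNA replication and all 25 of mitosis were lower, with medians of -3.92 and -5.78 and camera adjusted p of 6.47e-43 and 1.31e-65 (adjusted p 0.00122 and 0.000893 with an estimated correlation). The polo kinase gene PLK1 fell by 6.84. The histone genes HIST1H1B, HIST1H2AL, HIST1H3G and HIST2H3C were among the lowest 10, and how reads that match several histone genes were counted is not known. MMP1 fell by 9.29 ± 0.15, and ROBO4, an endothelial guidance receptor, had no counts after the drugs and was at least 451-fold lower. MYEOV and the receptor gene GPR3 completed the lowest 10. Counts adjusted over the list alone were the same for these lists.

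Immune and epithelial genes rose in control cells with the drugs. Antigen presentation went 15 higher and 0 lower of 15 (camera adjusted p 9.55e-17, and adjusted p 0.00761 with an estimated correlation), and interferon genes 23 higher and 0 lower of 25 (adjusted p 8.85e-12, and adjusted p 0.0264 with an estimated correlation), both the same adjusted over the list alone. HLA-B rose by 6.23 and IFI6, an interferon-induced membrane protein, by 5.03. C3, the central complement component, rose from 0.305 to 1711 CPM (log2 fold change 12.49). Epithelial genes went 10 higher and 0 lower of 12, also adjusted over the list alone (adjusted p 9.62e-06, and adjusted p 0.0422 with an estimated correlation). The adhesion gene CDH1, encoding E-cadherin, went from 1 count to 623 (ratio 527, 94.2 to 20800). Against no counts at day 0, the placental phosphatase ALPP was at least 2190-fold higher, CAPN6 at least 729-fold, MMP28 at least 580-fold, CYP4B1 at least 394-fold, CHI3L1 at least 361-fold, the mucin MUC16 at least 282-fold, KRT4 at least 206-fold and CSF3R at least 196-fold. The epithelial factor ELF3 had a ratio of 2660 (477 to 105000). How reads that match ALPP and related phosphatase genes were counted is not known, and CHI3L1, ELF3 and KRT4 lie in stretches shifted between the kinds of cell.

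Other lists called upward in control cells after the drugs were xenobiotic and aldehyde metabolism with 10 higher and 3 lower of 15 (camera adjusted p 4.69e-06, and adjusted p 0.0857 with an estimated correlation), lysosome and autophagy with 20 and 2 of 24 (adjusted p 2.55e-05, and adjusted p 0.105 with an estimated correlation) and the unfolded protein and stress response with 14 and 1 of 20 (adjusted p 0.00111, and adjusted p 0.105 with an estimated correlation). CDK inhibitors and p53 targets went 10 higher and 4 lower of 14 (adjusted p 0.0089, and adjusted p 0.197 with an estimated correlation). TP53INP1, a p53 target, rose by 4.66. Inflammatory genes went 10 higher and 9 lower of 20 (adjusted p 0.0228, and adjusted p 0.277 with an estimated correlation). These counts were the same adjusted over the list alone. Mesenchymal genes went 11 higher and 9 lower of 22 (11 and 10 adjusted over the list alone; adjusted p 0.0238, and adjusted p 0.0857 with an estimated correlation). The collagen gene COL3A1 rose from 10.5 to 2730 CPM, whereas vimentin (VIM) fell by 2.35. AHR rose by 1.66 ± 0.10 (adjusted p 4.55e-09) and ARNT by 0.83. The AHR target list went 13 higher and 4 lower but did not rank apart (adjusted p 0.158). In all, 10380 genes were called, 5291 higher and 5089 lower, and 5108 changed at least 2-fold.

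Drugs against day 0 in the labelled knockout asks how those cells respond to the same treatment. Drugs and time are again joined, and the counts again came in separate tables. DUSP6 and SPRY4 had no counts after the drugs and were at least 446-fold and 586-fold lower, CCND1 fell by 5.71, and ETV4 had a ratio of 735 (203 to 6070). All 27 replication and 25 mitotic genes were lower, also adjusted over the list alone (adjusted p 8.48e-51 and 7.45e-65, and adjusted p 6.78e-05 for each with an estimated correlation). ERK output went 1 higher and 16 lower of 19 (1 and 17 adjusted over the list alone; adjusted p 4.7e-21, and adjusted p 0.0163 with an estimated correlation). AHR itself did not pass the test (0.14 ± 0.10, adjusted p 0.248), although it did without labelled knockout replicate 2 of day 0 (adjusted p 0.0403). AHR targets went 5 higher and 5 lower, also adjusted over the list alone (adjusted p 0.705).

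Of 15 lists called in the labelled knockout after the drugs, 10 were also called with an estimated correlation. Glycolysis and hypoxia went 23 higher and 1 lower of 25 (adjusted p 2.75e-08, and adjusted p 0.0163 with an estimated correlation), and NDRG1, a hypoxia-induced gene, rose by 2.77. Antigen presentation went 12 higher and 1 lower of 15 (13 and 1 adjusted over the list alone; adjusted p 1.31e-06, and adjusted p 0.0163 with an estimated correlation), and HLA-B rose by 2.67. Xenobiotic metabolism, the stress response, lysosome, epithelial and mesenchymal lists were called upward too, with adjusted p of 5.77e-07, 2e-06, 6.13e-07, 0.000176 and 0.00169 (adjusted p 0.00432, 0.0235, 0.0212, 0.0325 and 0.0212 with an estimated correlation). The smooth-muscle actin gene ACTA2 rose by 6.10. The calls lost with an estimated correlation were inflammatory genes upward (adjusted p 0.000826, then adjusted p 0.152), oxidative phosphorylation upward (0.0159, then adjusted p 0.431), CDK inhibitors and p53 targets upward (0.0488, then adjusted p 0.232), YAP/TEAD targets downward (0.0488, then adjusted p 0.182) and endothelial genes downward (0.0488, then adjusted p 0.152). Connective tissue growth factor (CTGF), a YAP target, fell by 3.13. Interferon genes went 15 higher and 6 lower of 25 (16 and 6 adjusted over the list alone; adjusted p 0.0564). Of the control's highest 10, CYP4B1 alone did not pass (adjusted p 0.609). In all, 10597 genes were called, 5324 higher and 5273 lower, and 5225 changed at least 2-fold. Scaling by total counts moved the median by -0.169, and 4383 genes were then higher and 6324 lower.

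**Figure D4:**
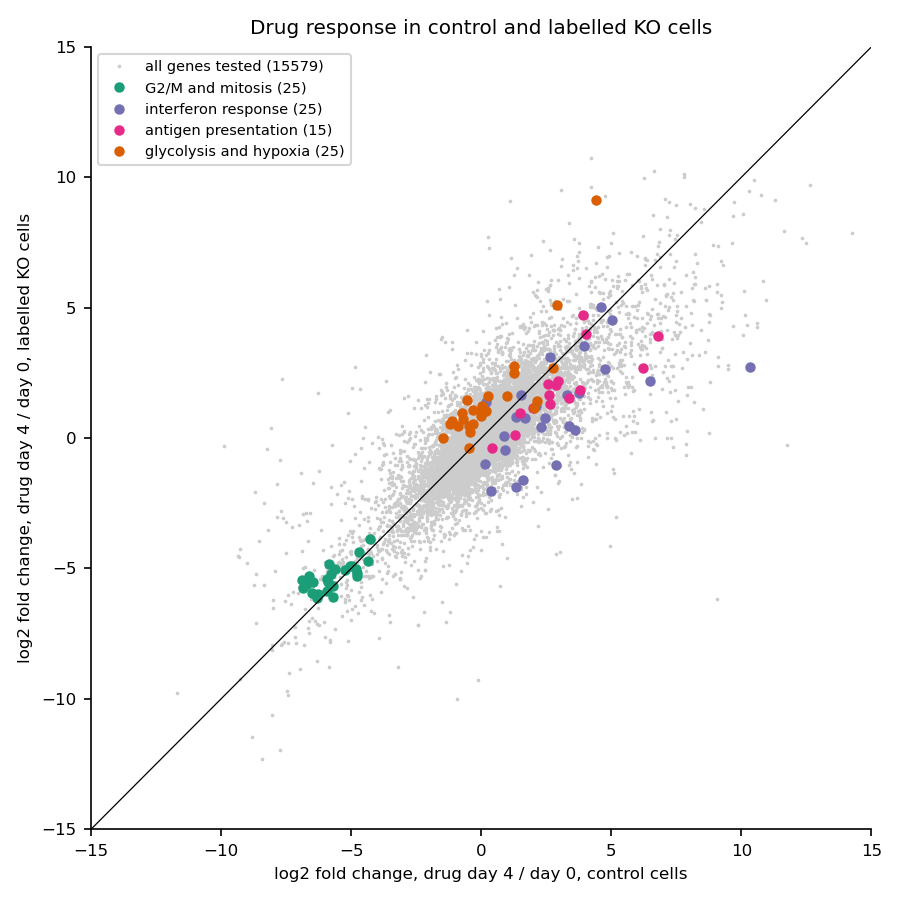
Log2 fold change after the drugs against day 0 in control cells (x axis) and in the labelled knockout (y axis) for 15579 genes (points), with 4 gene lists coloured. Of 8066 genes called in both, 3735 were higher in both and 3728 lower in both.

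The 2 drug responses shared no library. Of 8066 genes called in both, 3735 were higher in both, 3728 lower in both and 603 opposite, where calls made independently over all genes tested would give 1808 higher and 1722 lower in both. The correlation across genes was 0.79 (Spearman 0.75).

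The interaction asks whether the drug response itself differs between the labelled knockout and control. Interferon and antigen genes had lower drug responses in the labelled knockout. HLA-B rose by 6.23 in control and 2.67 in labelled knockout cells, an interaction of -3.56 (adjusted p 6.82e-10), and IFIT3 had an interaction of -3.20, going from 21.3 to 53.6 CPM in control and from 41.7 to 11.3 CPM in labelled knockout cells. The interferon list went 1 higher and 17 lower of 25 (2 and 19 adjusted over the list alone; camera adjusted p 5.58e-14, and adjusted p 0.0134 with an estimated correlation). Antigen presentation went 0 higher and 12 lower of 15, also adjusted over the list alone (adjusted p 3.01e-09, and adjusted p 0.0388 with an estimated correlation). Glycolysis and hypoxia went 21 higher and 2 lower of 25, also adjusted over the list alone (adjusted p 2.97e-14, and adjusted p 0.0134 with an estimated correlation), and HK2 (1.76) went from 69.7 to 30.3 CPM in control and from 61.3 to 90.1 CPM in labelled knockout cells. Oxidative phosphorylation went 16 higher and 2 lower of 23 (17 and 2 adjusted over the list alone; adjusted p 0.00111, and adjusted p 0.502 with an estimated correlation). The 3 endothelial genes were all lower, also adjusted over the list alone (adjusted p 1.1e-07, and adjusted p 0.0134 with an estimated correlation). ERK output went 6 higher and 8 lower of 19 and did not rank apart (median -0.01, adjusted p 0.668), nor did AHR targets, with 2 higher and 7 lower of 17 (median -1.07, adjusted p 0.135), or G1/S genes, with 5 higher and 9 lower of 27 (adjusted p 0.571), each the same adjusted over the list alone. The AHR target result is limited by genes near 0. In control cells CYP1B1 went from 237 to 5062 counts and CYP1A1 from 163 to 678. In the labelled knockout each went from 0 counts to 1, so the interaction of these genes could not be estimated. The list result therefore does not show that AHR targets responded alike in both kinds of cell. AHR had an interaction of -1.53 ± 0.14 (adjusted p 2.82e-06) and ARNT of -0.17 (adjusted p 0.369). In all, 5532 genes were called, 2669 higher and 2863 lower, and 2217 differed at least 2-fold. Scaled by total counts alone the median of all genes moved by -0.154 and 31.6% of called genes were higher, against 48.2%.

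**Figure D5:**
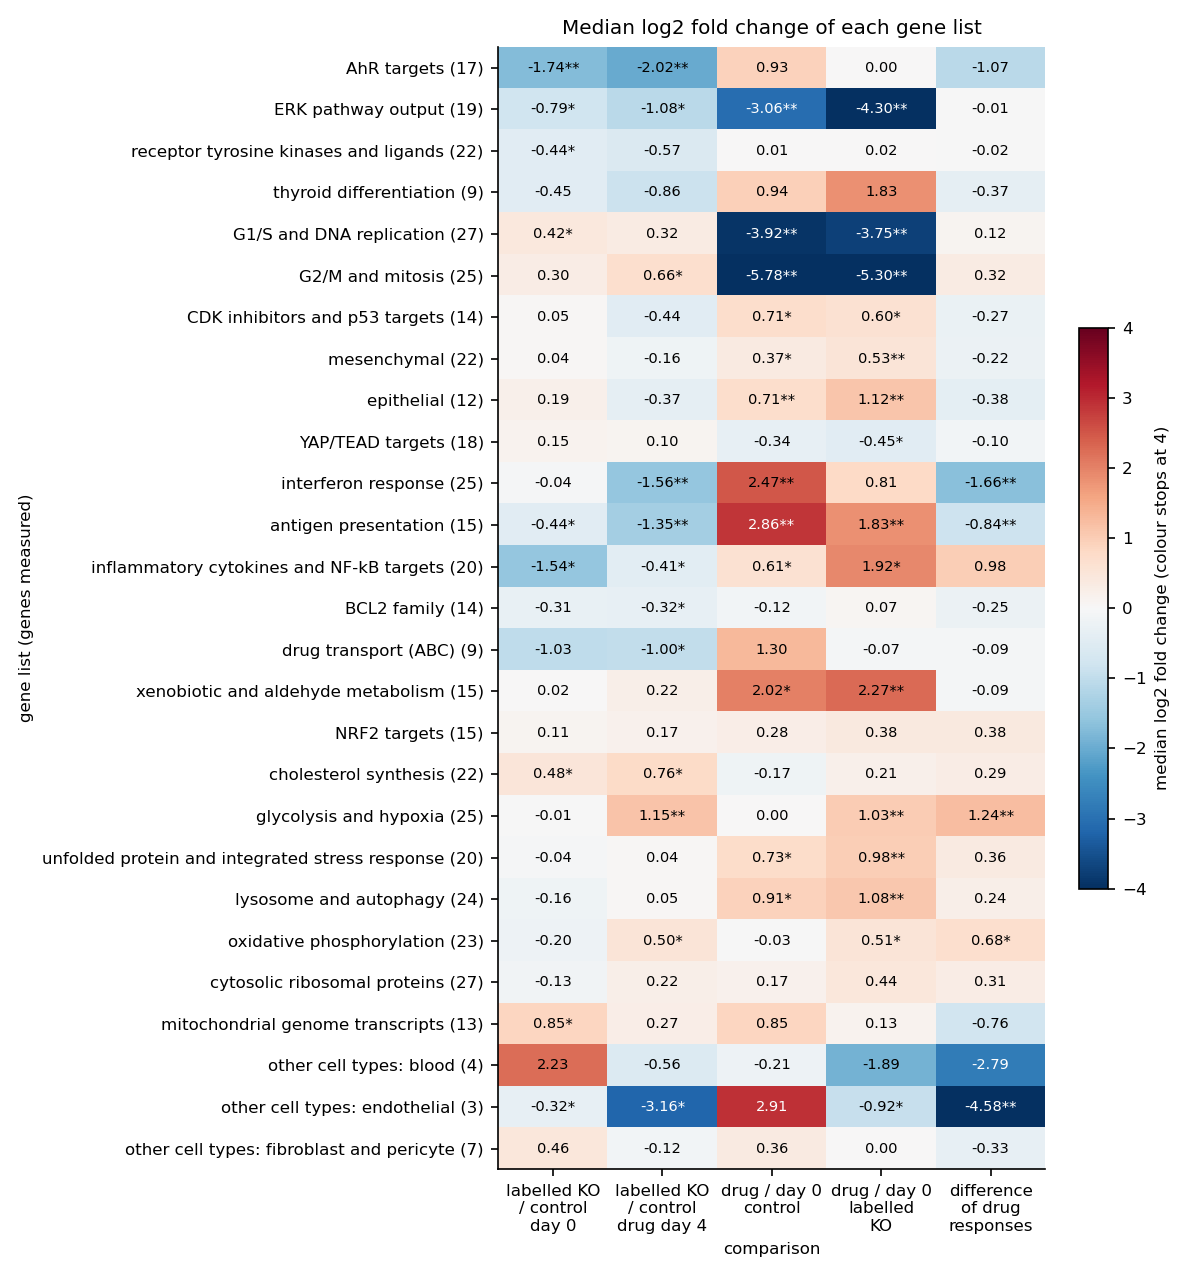
Median log2 fold change (colour, stopping at 4) of the gene lists with more than 1 gene measured (vertical) in 5 comparisons (horizontal), with 1 star for lists called by camera and a pair for those also called with an estimated correlation. The mitotic list has the lowest median, -5.78, after the drugs in control cells.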

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

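Comparisons, gene lists, thresholds and the tests of other sample splits were fixed before the data were examined. ARNT was chosen after its values were seen. The tests of AHR and of ARNT transcripts, which both use ARNT, were written before those tests were run. The test of lost ARNT function was chosen after the result was seen. The results in this part drew attention because the drug response differed between the labelled knockout and control by a test of the difference itself.

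The interaction called 5532 genes. AHR itself had an interaction of -1.53, since it rose with the drugs in control cells and did not pass the test in the labelled knockout, except without labelled knockout replicate 2 of day 0 (0.23, adjusted p 0.0403). Lists called were interferon response (adjusted p 5.58e-14), antigen presentation (3.01e-09), glycolysis and hypoxia (2.97e-14), oxidative phosphorylation (0.00111) and endothelial genes (1.1e-07), and the oxidative phosphorylation call was lost with an estimated correlation (adjusted p 0.502). Of the 3 endothelial genes, EMCN and PECAM1 had means of at most 4.60 CPM in any group, and the EMCN call was lost without labelled knockout replicate 1 of day 0 (adjusted p 0.0553).

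Genes with the lowest interaction were mostly those that the drugs switched on in control cells. CYP4B1 (-12.04) went from 0 to 24.4 CPM in control and from 0.438 to 0.359 CPM in labelled knockout cells, and its fitted value depends on the prior count. MXRA5 (-6.84) reached 49.2 CPM in control and 0.240 CPM in labelled knockout cells after the drugs, and its call was lost without labelled knockout replicate 3 of day 0 (adjusted p 0.0556). SUSD2 (-6.82) reached 62.4 and 2.95 CPM and ALPP (-6.38) 137 and 56.9 CPM. ALPP had 0 counts in control cells at day 0, so its fitted value depends on the prior count as well. H19 (-6.35) rose in both, from 0.169 to 94.7 CPM in control and from 54.0 to 364 CPM in labelled knockout cells.

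Genes with the highest interaction had lower means at day 0 in the labelled knockout, apart from C1QL1. MMP1 (5.01) and MMP3 (4.94) fell further in control cells, and the peroxisomal oxidase ACOX2 (5.50) went from 13.5 to 0.250 CPM in control and from 3.58 to 2.94 CPM in labelled knockout cells. The sphingosine kinase SPHK1 (4.58) went from 36.2 to 3.15 CPM in control and from 11.2 to 23.8 CPM in labelled knockout cells. The adhesion receptor ADGRG1 (4.79) went from 78.9 to 36.4 CPM in control and from 6.42 to 84.1 CPM in labelled knockout cells. C1QL1 (4.98) went from 0.595 to 1.54 and from 1.15 to 94.4 CPM.

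Of 200 possible splits that keep each state's libraries together, 100 were drawn, and 1, the real one, gave as many as 5532 genes. The highest other split gave 4577. It belongs to 10 draws that kept the drug groups intact and mixed the day 0 libraries (median 3348), whereas 8 draws that kept the day 0 groups intact and mixed the drug libraries reached at most 615 (median 482), and 81 draws that mixed both reached at most 4. These high counts point to the structure of the samples, because a split that keeps one state's groups still carries that state's difference. Mixing labelled knockout and control libraries also adds their difference to the spread within groups, so these splits do not tell whether chance is excluded for the interaction. For the other 4 comparisons 10 splits exist, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each. The real value and the highest other split were 6712 and 1 for labelled knockout against control at day 0, 8382 and 0 after the drugs, 10380 and 0 for the drugs in control cells and 10597 and 0 in the labelled knockout.

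The guide printed in the labels matches ARNT and not AHR, which leaves open which gene was edited. That the drugs leave the labelled knockout without ARNT function is argued against by 9 genes that hypoxia-inducible factors switch on with ARNT, whose median log2 fold change after the drugs was 1.15, with 7 higher and 2 lower; the related ARNT2, chosen after its values were seen, was at 0.258 ± 0.224 CPM there. These 9 genes belong to the glycolysis and hypoxia list, already seen to be higher after the drugs, and are not separate support. An edit is carried into both states, so the values bear on an ARNT edit that abolishes function, whereas an edit that leaves function stays open. A test written before it was run asked for ARNT and the 9 genes to be called lower in both states, and it could not tell. At day 0 ARNT changed by 0.12 without passing the test, and the same 9 genes had a median of 0.09 with 2 higher and 1 lower. An AHR edit with a misprinted sequence is consistent with AHR being lower in both states (-0.64 at day 0, the smaller change) while ARNT was not called lower in either, except after the drugs when scaled by total counts alone. That is weak support, since 1587 of the 15579 genes tested were called lower in both states. An edit that leaves the ARNT transcript in place would also not be seen in its counts. The shifted run on chromosome 1 begins at 154155308, beyond the guide match at 150839529, and whether they are related was not tested. The near silence of CYP1A1 and CYP1B1 would follow from losing either partner and does not separate these explanations, and no sequence of the edited site was analysed here.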

How the results depend on the processing

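Removing 5 small structured RNAs before scaling was chosen after seeing the data, and every other alternative was planned. No called gene named in the text reversed its direction under any alternative, and no called list changed the sign of its median under another scaling, while several uncalled lists did. The balance of calls at day 0 turned, to 2133 higher and 2379 lower with only its 6 libraries, to 3253 and 3259 with total counts and to 732 and 1144 with a change of at least 2-fold. It also turned for drugs in the labelled knockout with total counts (4383 and 6324) and a mean of 1 CPM (4814 and 4894), and for the interaction without labelled knockout replicate 2 of the drug group (2635 and 2608).

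Counts of called genes stayed within 1.5 times their value under RLE size factors, total counts, no count filter, a filter at a mean of 1 CPM, DESeq2, limma-voom, fits of only the 6 libraries compared, and removal of the small RNAs. For labelled knockout against control at day 0 they ran from 4512 with only its 6 libraries to 6834 with DESeq2, and for the interaction from 5024 without a count filter to 5859 with total counts. Stricter thresholds lowered counts by construction. At an adjusted p under 0.01, 4398 genes were called for labelled knockout against control at day 0 and 3407 for the interaction. With a change of at least 2-fold, 1876, 2987, 5108, 5225 and 2217 genes were called for labelled knockout against control at day 0 and after the drugs, drugs in control cells, drugs in the labelled knockout and the interaction.

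Leaving out each library in turn gave 5334 to 7590 genes for labelled knockout against control at day 0, 7258 to 7670 after the drugs, 9675 to 10112 for drugs in control cells, 9816 to 10653 in the labelled knockout and 4535 to 6349 for the interaction. The highest day 0 and interaction counts came without labelled knockout replicate 1 of day 0, and the cause was not tested. Without replicate 2 of that group, whose label lacks the second read, 5967, 10536 and 5682 genes were called for the 3 comparisons that use it. With the replicate number as a block, 6334, 8042, 10181, 10379 and 5157 genes were called, and interferon response in the labelled knockout after the drugs became called (adjusted p 0.0446, against adjusted p 0.432 with an estimated correlation and no block). Residual correlations of libraries with the same replicate number ran from -0.25 to 0.27, and 4 of 18 pairs exceeded 0.1. Libraries with different numbers were not compared in this way, so these values do not tell whether the numbers pair libraries.

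Of named genes, leaving out a library ended calls of the interaction for ABCC2, ABCC3, AHRR, DUSP6, EGR1, EMCN, EPHA4, ETV5, FOS, MT-CO1, MT-CO3, MXRA5 and SPRY4. It ended calls at day 0 for ABCG2, CDKN2C, HBB and MT-ND2, for drugs in control cells for PDPN and TIPARP, and for drugs in the labelled knockout for HBB and LRAT. Over all named genes and libraries left out, 83 results were weaker, 11 stronger and 5228 the same, and the cause was not tested. Total counts ended calls after the drugs for DUSP4 (adjusted p 0.0545), MYC (adjusted p 0.119), RPL30, RPL7A and RPS3, and made ARNT pass (adjusted p 0.0419). With limma-voom the interactions of CYP1B1 (adjusted p 0.00531), CYP1A2 (0.00598) and ALDH3A1 (0.000447) passed, and that of ALDH3A1 also passed with DESeq2 (adjusted p 0.0243). In the labelled knockout these genes had 0 counts at day 0 and at most 2 after the drugs. Their fitted interactions therefore depend on how a method treats counts near 0. Whether that alone made these calls differ was not tested. With an estimated correlation 28 list calls were lost and 112 results kept their side of the threshold, and fry, which does not compare a list with other genes, added 52 calls.

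Depth limits rare transcripts, since 0 counts of a gene in a library allow up to 0.235 CPM. In counts simulated for the interaction with the real depth, spread and number of libraries, 9% of genes changed by 0.5 on the log2 scale were recovered. Only 200 genes were changed there, while 5532 were called in the data. The adjusted threshold was therefore stricter in the simulation, and this share is likely too low for the real data. Depth was not varied on its own.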

Other observations

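The tests of copy number, of shared HBB expression and of blood or erythroid reads were chosen after the results were seen, as were the scan along chromosomes, its threshold and the choice of chromosome 14 from all chromosomes.

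Survival and transport genes differed between labelled knockout and control after the drugs. The BCL2 family went 3 higher and 8 lower of 14, also adjusted over the list alone (camera adjusted p 0.0197, and adjusted p 0.253 with an estimated correlation). BMF changed by -5.93, BID, which links death receptors to mitochondria, by -1.16 and the survival gene BCL2L1 by -0.81. Drug transporters of the ABC family went 1 higher and 5 lower of 9 (1 and 6 adjusted over the list alone; adjusted p 0.00746, and adjusted p 0.0714 with an estimated correlation). The multidrug exporter ABCG2 changed by -3.73, ABCC3 by -5.11 and the cholesterol exporter ABCA1 by -2.27. The 3 endothelial genes were lower (adjusted p 0.016, and adjusted p 0.163 with an estimated correlation), also adjusted over the list alone.

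Thyroid genes went in several directions. GLIS3, a thyroid transcription factor, stood at 16.3 CPM in control and 135 CPM in labelled knockout cells after the drugs, and PAX8, which specifies thyroid cells, at 0.957 and 4.19 CPM. DIO2, which activates thyroid hormone, and the thyroid factor NKX2-1 were lower (-1.84 and -1.26), and both lie on the shifted chromosome 14. The list went 3 higher and 6 lower of 9, also adjusted over the list alone, and did not rank apart (median -0.86, camera adjusted p 0.94). NRF2 targets did not either (7 higher and 5 lower of 15, adjusted p 0.119). The same held for CDK inhibitors and p53 targets (2 and 8 of 14, adjusted p 0.169), mesenchymal genes (9 and 9 of 22, median -0.16 with the test upward, adjusted p 0.441), epithelial genes (1 and 6 of 12, adjusted p 0.333), YAP/TEAD targets (8 and 6 of 18, adjusted p 0.791) and xenobiotic metabolism (7 and 5 of 15, adjusted p 0.94). Stress response (10 and 9 of 20, adjusted p 0.218), lysosome (9 and 5 of 24, adjusted p 0.678), ribosomal proteins (7 and 3 of 27, adjusted p 0.441), and mitochondrial transcripts (0 and 0 of 13, adjusted p 0.678) were not called. Receptor tyrosine kinases and their ligands (5 and 14 of 22, adjusted p 0.241) were not called either. YAP/TEAD, NRF2, stress response and lysosome medians changed sign when scaled by total counts alone, and ribosomal proteins then went 0 higher and 4 lower. Of lists that mark other cell types, blood (0 and 2 of 4, adjusted p 0.0592) and fibroblast and pericyte (1 and 2 of 7, adjusted p 0.484) were not called. Many of these markers are also made by tumour cells, and the source of the CDH5 reads was not tested.

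Chromosome 14 genes were lower in the labelled knockout in both states. A trend with GC content or transcript length as the whole cause is argued against, since removing it left the relative median at -0.57 at day 0 and -0.51 after the drugs, with values for 430 of 430 genes. A copy-number difference between both kinds of cell is consistent with the relative median in each of the 6 labelled knockout libraries, the highest of which was -0.50, and with drug effects of only 0.06 and 0.05 on these genes. Such a difference may have arisen in either population before or after the guide was introduced, and DNA was not analysed here. A regulatory difference that spans the chromosome was not tested.

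HBB had 0, 3576 and 3065 counts in labelled knockout replicates 1, 2 and 3 of day 0, 87 counts in replicate 2 after the drugs and at most 23 in any other library, that one being control replicate 3 of day 0, where all globin transcripts came to 250 counts. Expression shared by these cells is argued against, because the 0 counts of replicate 1 allow at most 0.12 CPM, against 278 and 150 CPM in the other libraries. Reads from blood or erythroid cells stay open: 7 of their abundant transcripts together came to 0.14% and 0.392% of the HBB counts, all from PTPRC, which had more counts (19) in the library without HBB. Carry-over from another library is a further possible source that was not tested.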
